A study of Oryza sativa with 12 samples.

How the data were processed

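RNA-seq libraries were made from leaves and roots of hydroponically grown rice (Oryza sativa) seedlings that were 1 month old. The wild type (WT) was the cultivar ZH11, as the sample titles name it, and the other genotype was a line labelled f3h. The labels call that line a knockdown, whereas the design text of the series calls the material CRISPR mutants. Neither source used here says which of the flavanone 3-hydroxylase loci was targeted. Each of the 4 groups (WT leaf, f3h leaf, WT root, f3h root) had 3 libraries, 12 in all. The labels do not say whether the 3 libraries of a group came from separate plants or pools, so every p-value measures only the spread between these libraries, which may be technical.

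The authors deposited raw read counts per gene, as whole numbers with no normalization. Per the submitters' processing notes, fastp, HISAT2, featureCounts and DESeq were used, with no versions, and the genome build, the annotation and the strand setting of the counting are not given in the sources used here. The labels' protocols describe total RNA and an mRNA library kit. The deposited counts covered 37960 genes, of which 37849 carried Os locus identifiers and 111 carried other names, mostly of organelle genes. Each of the 12 columns matched the label of 1 sample. Genes of near-identical families, such as the chlorophyll a/b-binding proteins, the RAB16 dehydrins and the small heat shock proteins, may share reads, and their separate values are uncertain to that extent.

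The table does not pair locus identifiers with gene names. The reference table of gene names used here (assembly ASM3414082v1) matched 100 of the identifiers directly, 1 of them an Os locus. Names were therefore taken from 213 pairs of a name and a locus that had been written into 17 gene lists before the data were examined. A name was printed only where the reference held it on the chromosome carried in the locus identifier and within 10% of the chromosome length of the place that the identifier implies. The reference held 130 of the names, and 127 passed. After names were shuffled over loci 1000 times, a mean of 5.35 and at most 14 passed. Members whose names were not found in the reference stayed in the lists and are counted there, but are not named, except for the flavanone 3-hydroxylase loci, which are given by locus. The tolerance was widened to 10% after the outcome of the name check had been seen. No coordinates are printed, since the builds are not known to be the same. Gene length and GC content could not be paired with the loci and were not used here.

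Total counts were 31171931 to 37821918 in the leaf libraries and 23740780 to 29687320 in the root libraries. Intervals and floors cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules. A count of 0 over the 3 libraries of a group was read as a level below 3 counts of the group's total. For genes with 1 to 3 counts in a group a ratio is given with its exact 95% binomial interval. Levels are given as CPM, the usual scaling of a gene's counts to the library total, as mean ± SD over 3 libraries.

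Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, and the quasi-likelihood test, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. All adjusted p-values of genes come from this test unless another tool is named. The f3h effect was fitted separately in leaf and in root on the 6 libraries of the organ. The difference between these effects was fitted as an interaction term on all 12 libraries. WT root was compared with WT leaf with a further limit of an absolute log2 fold change of at least 1. An exact permutation test of 3 against 3 libraries cannot give a two-sided p below 0.1, so none was used. Errors of log2 fold changes are standard errors derived from the F statistic of the test. Lists with at least 3 tested members were tested with camera from limma 3.58.1 on voom values, against all other tested genes, with a preset correlation of 0.01 and adjustment over the 17 lists. The same test was run with a correlation estimated for each list, and fry was run as an alternative.

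Before the data were examined, the rule for the named genes was fixed. It took the flavanone 3-hydroxylase loci, the 8 largest rises and 8 largest falls among named genes past the threshold with an average log2 CPM of at least 1 and no overlap between the groups' libraries, and up to 4 members of each list with the smallest p. It took 5 and 5 for the comparison of organs and for the interaction, and 5 genes called in the same direction in both organs. As names could be checked only for list members and organelle genes, the rule was applied to those. At most 2 rising and 2 falling loci without a name are added per comparison. The lists built from gene descriptions could not be run, since no descriptions were at hand.

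The procedure was tested on simulated counts drawn from the means, dispersions and library sizes of these libraries, with genes changed by known folds. In the leaf simulation (22102 genes tested) 21.9% of genes changed 1.5-fold, 56.1% of those changed 2-fold and 83.3% of those changed 4-fold were recovered. In the root simulation (24227 genes) the shares were 40.3%, 80.6% and 87.5%. In the simulated interaction (25640 genes) they were 7.58%, 50.0% and 69.4%, and in the simulated organ comparison (24815 genes), run without its fold limit, 10.9%, 47.0% and 79.0%. False calls made up 3.64%, 3.52%, 2.41% and 3.33% of all calls in these simulations. Far fewer genes were changed than were called in the data, for example 66 by 2-fold in leaf. Before the changes, each gene had the same mean in all groups, so leaf and root did not differ. The shares therefore need not carry over to the data. Alternatives were another normalization (DESeq2 size factors, upper quartile), other count filters, DESeq2 1.42.0, limma voom, a fit of all 12 libraries, a fold limit, the replicate number as a block, and leaving out each library in turn. Python 3.11.15 was used for the name check and, with matplotlib 3.10.9, for the plots.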

Results

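Gene expression was measured by RNA-seq in leaves and roots of 1-month-old rice seedlings of the wild type (WT, cultivar ZH11) and of an f3h line, named after flavanone 3-hydroxylase, an enzyme of flavonoid synthesis. Each genotype and organ was represented by 3 libraries. The libraries held 31171931, 35021116 and 33823138 counts in WT leaf, 36769588, 32314230 and 37821918 in f3h leaf, 27429014, 27317632 and 29687320 in WT root, and 25804026, 27917598 and 23740780 in f3h root. Log2 CPM of replicates correlated across genes, which are not independent replicates, with r between 0.979 and 0.991, except that WT leaf replicate 1 correlated with replicates 2 and 3 at 0.967 and 0.964. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 5.49 or more), so all 12 were kept as separate libraries.

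The loci listed as flavanone 3-hydroxylase (F3H) genes were examined in every group, since the line is named after this enzyme. Of these, Os03g0122300 was listed only as F3H-like. Os10g0536400 stood at 53.7 ± 3.21 CPM in WT leaf and 85.3 ± 3.42 CPM in f3h leaf, a log2 fold change of 0.70 ± 0.09 (adjusted p = 0.000267), and at 35.3 ± 2.98 and 33.4 ± 1.66 CPM in WT and f3h root (adjusted p = 0.351). Os03g0122300 stood at 35.7 ± 9.71 CPM in WT leaf and 23.9 ± 1.60 CPM in f3h leaf (log2 -0.55 ± 0.17, adjusted p = 0.0338), a call that was lost when f3h leaf replicate 1, 2 or 3 was left out (adjusted p = 0.0730, 0.123 and 0.115), and at 67.9 ± 2.96 and 73.9 ± 3.44 CPM in the roots (adjusted p = 0.258). Os04g0667200 had 0 counts in WT leaf and 4 in f3h leaf, and stood at 1.13 ± 0.166 against 0.935 ± 0.475 CPM in WT and f3h root (adjusted p = 0.657). Os04g0662600 had 2, 20 and 17 counts in the WT root libraries and 0 in each f3h root library, at least 11.9-fold lower over the group, but was too low to be tested. The names of these 4 loci were not found in the reference, and which locus was targeted is not stated. If the line is CRISPR edited, an RNA level does not check it, since edited genes can still be transcribed. If it is a knockdown, as the labels say, a lower RNA level would be looked for. Among the tested loci only Os03g0122300 passed as lower, in leaf, by the call that was not stable.

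The leaf comparison asked which transcripts differ between the genotypes in leaf. In the iron uptake list, 7 of 11 tested members rose and 1 fell in f3h leaf (camera adjusted p = 0.00304, and adjusted p = 0.256 with an estimated correlation). NAS2 (Os03g0307200) and NAS1 (Os03g0307300), which encode nicotianamine synthases, rose from 2.96 ± 0.458 to 47.2 ± 8.27 CPM (log2 4.02 ± 0.18, adjusted p = 5.93e-07) and from 1.68 ± 0.385 to 20.6 ± 3.80 CPM (log2 3.64 ± 0.22). In the phytoalexin synthesis list, 5 of 9 members fell and 1 rose (camera adjusted p = 0.0165, and adjusted p = 0.256 with an estimated correlation). The copalyl diphosphate synthases of diterpenoid synthesis among those that fell were CPS2 (Os02g0571100), from 30.3 ± 4.27 to 2.09 ± 0.589 CPM (log2 -3.83 ± 0.22), and CPS4 (Os04g0178300), from 4.29 ± 0.131 to 0.146 ± 0.0764 CPM (log2 -4.79 ± 0.39). The chlorophyll a/b-binding protein gene CAB2R (Os01g0600900), which took the most counts of any gene in each WT leaf library, fell from 16679 ± 1875 to 5716 ± 57.3 CPM (log2 -1.52 ± 0.10).

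Of the iron uptake genes, 8 rose and 1 fell when adjusted over the list alone. The metal transporters NRAMP1 (Os07g0258400, log2 1.20 ± 0.11) and YSL2 (Os02g0649900, log2 0.97 ± 0.10) were among those that rose, and NAAT1 (Os02g0306401), a nicotianamine aminotransferase of phytosiderophore synthesis, fell. In the low oxygen list, 3 of 5 members rose. The haemoglobin gene HB1 (Os03g0233900) had no count in WT leaf and 4.05 ± 0.621 CPM in f3h leaf, at least 136-fold higher. SUS1 (Os03g0401300), a sucrose synthase, rose by a log2 fold change of 2.39 ± 0.26 and the alcohol dehydrogenase ADH1 (Os11g0210300) by 1.34 ± 0.12. Of the antioxidant enzymes, 3 of 8 rose, namely the superoxide dismutases SODCC2 (Os07g0665200, log2 0.82 ± 0.09) and SODA (Os05g0323900, log2 0.56 ± 0.09) and the catalase CATB (Os06g0727200, log2 0.93 ± 0.14). Both lists passed camera (adjusted p = 0.0137 and 0.0194), and neither did with an estimated correlation (adjusted p = 0.256 for each). The counts of both were the same when adjusted over the list alone.

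Of the circadian clock genes, 7 of 12 fell in f3h leaf, also when adjusted over the list alone. The pseudo-response regulators PRR95 (Os09g0532400, from 475 ± 39.3 to 220 ± 2.72 CPM, log2 -1.08 ± 0.08), PRR73 (Os03g0284100, log2 -0.87 ± 0.12) and PRR37 (Os07g0695100, log2 -0.72 ± 0.11) and the evening gene GI (Os01g0182600, log2 -0.52 ± 0.09) were among them, while LHY (Os08g0157600) was at a log2 fold change of -0.13 and did not pass. The list passed camera (adjusted p = 0.00304), but not with an estimated correlation (adjusted p = 0.256). Its members had a median log2 level 0.22 higher in WT leaf replicate 1 than in replicates 2 and 3, and the list passed without that library too (adjusted p = 0.000937). The counts of the phytoalexin list were the same when adjusted over the list alone. The momilactone gene CYP99A3 (Os04g0178400) fell by 2.15 ± 0.35 on the log2 scale, and KSL10 (Os12g0491800), a diterpene synthase, had no count in f3h leaf, at least 38.8-fold lower.

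In the photosynthesis list, 10 of 22 members fell and 2 rose in leaf over all genes tested, and 12 fell and 2 rose when adjusted over the list alone. RCA (Os11g0707000), which encodes Rubisco activase, rose (log2 0.50 ± 0.09). CAB1R (Os09g0346500) stood at 9987 ± 3537 CPM in WT leaf and 8063 ± 85.1 CPM in f3h leaf and did not pass (adjusted p = 0.368), but passed without WT leaf replicate 1 (log2 -0.54, adjusted p = 4.36e-14). The list median was -0.28, camera gave an adjusted p of 0.0194, with an estimated correlation the adjusted p was 0.573, and with the 3 members whose names were checked it was 0.791. Its median level was 0.17 lower on the log2 scale in WT leaf replicate 1 than in the other WT leaf libraries, and root cell markers, with 1 riser and 1 faller among 5 tested members (also when adjusted over the list alone), did not pass camera in leaf (adjusted p = 0.848). Of the chlorophyll synthesis genes, PORA (Os04g0678700), a protochlorophyllide reductase, fell from 81.9 ± 5.17 to 29.0 ± 1.88 CPM (log2 -1.47 ± 0.10), PORB (Os10g0496900) fell (log2 -0.49 ± 0.08) and CHLD (Os03g0811100) rose (log2 0.59 ± 0.09), among 6 tested.

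Other lists held changed members in leaf without a shift of the list past the camera threshold. In flavonoid synthesis, 4 of 9 rose and 3 fell (adjusted p = 0.603). Chalcone synthase CHS1 (Os11g0530600) rose from 5.43 ± 0.942 to 24.9 ± 1.48 CPM (log2 2.23 ± 0.15), and chalcone isomerase CHI (Os03g0819600) was at a log2 fold change of 0.18 ± 0.21 and did not pass. In phenylpropanoid and lignin synthesis, 7 of 17 rose and 4 fell (adjusted p = 0.848). CAD2 (Os02g0187800, log2 0.82 ± 0.10), a cinnamyl alcohol dehydrogenase, and the ligase gene 4CL3 (Os02g0177600, log2 0.59 ± 0.10) rose, and another ligase gene, 4CL2 (Os02g0697400) fell from 4.09 ± 0.950 to 0.351 ± 0.0952 CPM (log2 -3.49 ± 0.35). Among water deficit and abscisic acid genes, 4 of 12 rose and 2 fell (adjusted p = 0.458). LEA3 (Os05g0542500), a late embryogenesis abundant protein gene, rose from 1.13 ± 0.292 to 11.9 ± 1.64 CPM (log2 3.43 ± 0.23), the proline synthesis gene P5CS1 (Os05g0455500) from 15.2 ± 3.80 to 132 ± 3.47 CPM (log2 3.15 ± 0.17), and SALT (Os01g0348900), a salt-induced lectin gene, fell (log2 -2.11 ± 0.39). In jasmonate synthesis and signalling, 5 of 11 rose and 2 fell (adjusted p = 0.606), with the repressor gene TIFY11A (Os03g0180800) rising (log2 1.87 ± 0.22) and TIFY10B (Os07g0615200) falling (log2 -0.86 ± 0.09).

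In phosphate starvation, 4 of 7 rose and 1 fell in leaf (camera adjusted p = 0.201). SPX1 (Os06g0603600) and the galactolipid synthase MGD2 (Os08g0299400, log2 6.05 ± 0.71, from 0.0493 ± 0.0853 to 3.47 ± 0.533 CPM) rose. The 5 counts of MGD2 in WT leaf were all in replicate 3, so the size of its rise is uncertain. SPX2 (Os02g0202200) fell (log2 -1.77 ± 0.30). In nitrogen uptake and assimilation, 3 of 10 rose and 2 fell (adjusted p = 0.848). Nitrate reductase NIA1 (Os08g0468100) rose from 82.8 ± 4.52 to 265 ± 17.6 CPM (log2 1.71 ± 0.09), and the ammonium transporter AMT1;1 (Os04g0509600) fell (log2 -1.06 ± 0.10). Of the pathogenesis related and salicylate genes, 2 of 6 rose and 4 fell (adjusted p = 0.201), with the salicylate receptor gene NPR1 (Os01g0194300) falling (log2 -0.71 ± 0.16). In chlorophyll synthesis (adjusted p = 0.848) 1 of 6 rose and 2 fell, and in heat shock (adjusted p = 0.848) 1 of 6 fell, the chaperone HSP101 (Os05g0519700). No cell cycle gene among 5 passed edgeR on the leaf libraries (0 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma voom). CYCB2;1 (Os04g0563700), at 0.276 ± 0.109 and 0.616 ± 0.178 CPM in WT and f3h leaf, passed in the fit of all 12 libraries (log2 1.17, adjusted p = 0.0128). For the cell cycle list camera gave an adjusted p of 0.848. In each list of this and the preceding paragraph the counts were the same when adjusted over the list alone. Median, mean and test differed in sign for 6 leaf lists. In flavonoid synthesis the median was 0.18 and the mean -0.08 while camera pointed up. In phenylpropanoid synthesis (-0.07 and -0.02), nitrogen (-0.33 and 0.55) and water deficit (-0.08 and 0.52) camera pointed up. In heat shock (0.01 and -0.22) and chlorophyll synthesis (0.03 and -0.19) camera pointed down, and the heat shock median turned negative with upper quartile normalization.

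Over all genes, 4021 rose and 4167 fell in f3h leaf, 8188 of 22438 tested (36.5%). This share is the background against which the counts of called list members in leaf are to be read. With an absolute log2 fold change of at least 1, 1630 rose and 1810 fell. The libraries of the genotypes did not overlap for 52.3% of genes, where 10% would be so by chance. Among loci without a checked name, Os08g0410900 had no count in WT leaf and 29.7 ± 2.55 CPM in f3h leaf, at least 985-fold higher, and Os03g0226200 rose from 0.0832 ± 0.0989 to 778 ± 58.2 CPM. Os01g0663051 fell from 15.3 ± 1.72 CPM to no count, at least 547-fold lower, and Os03g0752500 from 10.3 ± 2.93 CPM to 3 counts over the group, a ratio of 371 with a counting interval of 127 to 1803. Without WT leaf replicate 1, which stood apart from the other replicates, 5721 genes rose and 5423 fell.

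**Figure D1:**
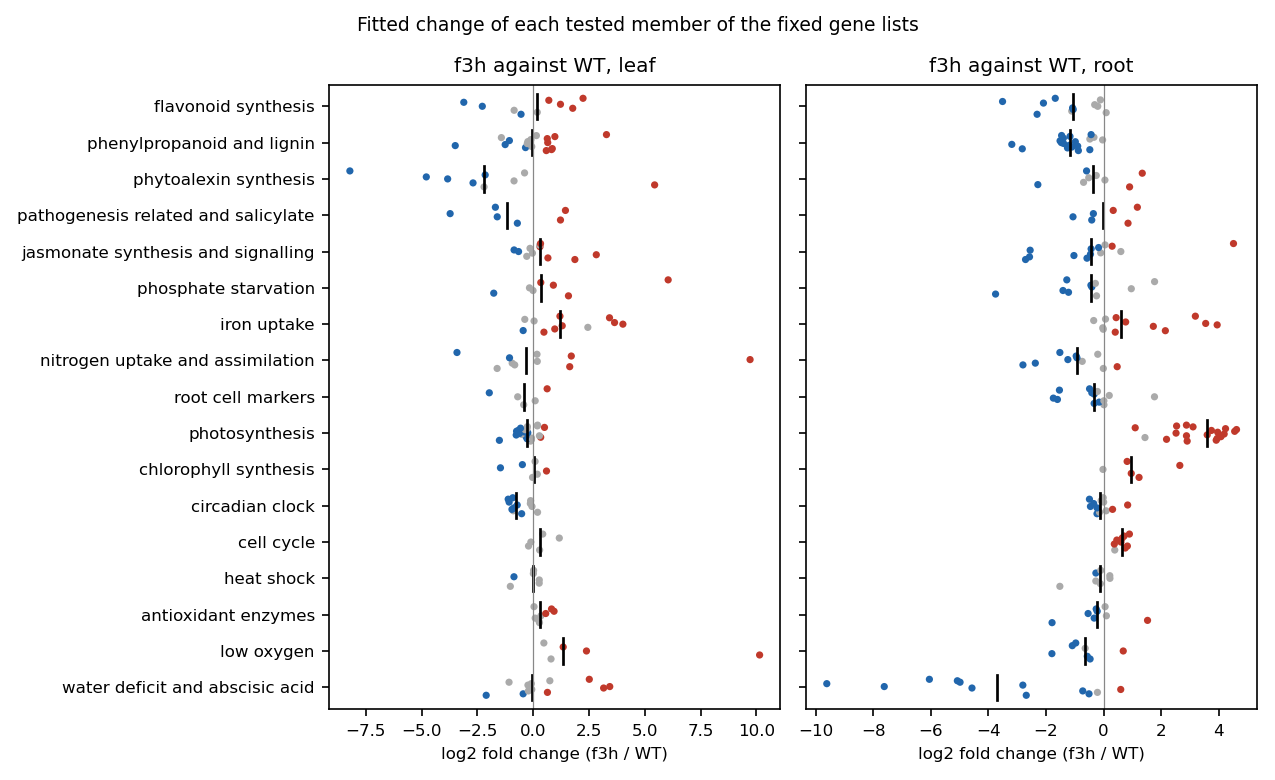
Log2 fold change (f3h over WT) of every tested member of the 17 fixed lists in leaf and in root, on separate scales. Points are genes, red where they rose and blue where they fell with an adjusted p under 0.05, grey otherwise, and black bars are list medians (photosynthesis -0.28 in leaf and 3.60 in root, water deficit -0.08 and -3.69); values of genes with no count in a group depend on the prior count.

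The root comparison asked the same of roots. In the water deficit and abscisic acid list, 10 of 12 members fell and 1 rose in f3h root (camera adjusted p = 3.34e-07, and adjusted p = 0.0587 with an estimated correlation). The dehydrin RAB16D (Os11g0453900) fell from 23.4 ± 2.03 CPM to 2 counts over the 3 libraries, a ratio of 908 with a counting interval of 251 to 7501. The transcription factor gene DREB1B (Os09g0522000) fell from 55.6 ± 3.38 to 0.282 ± 0.248 CPM (log2 -7.62 ± 0.23), and SALT from 908 ± 25.5 to 144 ± 3.51 CPM (log2 -2.68 ± 0.04). The nicotianamine synthase genes NAS2 and NAS1 rose, from 23.1 ± 1.45 to 364 ± 15.6 CPM (log2 3.95 ± 0.06) and to 208 ± 7.74 CPM (log2 3.55 ± 0.07). In phenylpropanoid and lignin synthesis, 16 of 19 members fell (camera adjusted p = 2.12e-15, and adjusted p = 0.0587 with an estimated correlation), such as the coumarate ligase gene 4CL5 (Os08g0448000), from 54.9 ± 2.41 to 20.4 ± 2.15 CPM (log2 -1.46 ± 0.09).

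The median log2 fold change of the water deficit list was -3.69, and its counts were the same when adjusted over the list alone. RAB16B (Os11g0454200, log2 -5.08 ± 0.40), RAB16C (Os11g0454000, log2 -4.99 ± 0.41), LEA3 (log2 -4.57 ± 0.28) and DREB1A (Os09g0522200, log2 -2.80 ± 0.18) fell, and P5CS1 rose (log2 0.60). In phenylpropanoid and lignin synthesis, 17 members fell when adjusted over the list alone. Besides 4CL5, 4CL3 (log2 -0.87 ± 0.05) and the alcohol dehydrogenase CAD2 (log2 -0.48 ± 0.05) were among those that fell over all genes tested. In flavonoid synthesis, 6 of 11 fell, also when adjusted over the list alone. CHI fell from 106 ± 9.24 to 52.3 ± 5.55 CPM (log2 -1.05 ± 0.08). CHS1 stood at 0.779 ± 0.383 and 0.245 ± 0.0111 CPM (adjusted p = 0.0479), a call lost with upper quartile normalization (adjusted p = 0.0509), without a count filter (adjusted p = 0.0940), under limma voom (adjusted p = 0.0830), with the replicate block (adjusted p = 0.0972) and without any of the 6 root libraries (adjusted p from 0.0508 to 0.290). The flavonoid list passed camera (adjusted p = 0.0192), but not with an estimated correlation (adjusted p = 0.167).

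In the iron uptake list, 8 of 12 members rose in root over all genes tested, and 8 rose and 1 fell when adjusted over the list alone. NAAT1 rose from 32.3 ± 2.85 to 147 ± 7.98 CPM (log2 2.15 ± 0.07) and the regulator gene IRO3 (Os03g0379300) rose (log2 0.77 ± 0.06), while the iron transporter IRT1 (Os03g0667500) was at a log2 fold change of -0.34 and did not pass. Camera gave an adjusted p of 1.37e-06, and the adjusted p was 0.0587 with an estimated correlation. Of the cell cycle genes, 8 of 9 rose, also when adjusted over the list alone, including the cyclin CYCB1;1 (Os01g0805600, log2 0.75 ± 0.09) and the kinases CDKB1;1 (Os01g0897000, log2 0.83 ± 0.11) and CDKB2;1 (Os08g0512600, log2 0.72 ± 0.10). The list's camera call (adjusted p = 0.000508) was lost with an estimated correlation (adjusted p = 0.124). Root cell markers did not move the same way, as 8 of 13 fell over all genes tested and 9 when adjusted over the list alone. CASP1 (Os04g0684300), which encodes a Casparian strip protein of the endodermis, fell from 86.0 ± 3.55 to 26.2 ± 1.82 CPM (log2 -1.74 ± 0.08), and the root hair cellulose synthase-like gene CSLD1 (Os10g0578200) fell from 21.0 ± 2.55 to 7.42 ± 0.982 CPM (log2 -1.53 ± 0.15). SHR1 (Os07g0586900, log2 -0.41 ± 0.07) and NRAMP5 (Os07g0257200, log2 -0.32 ± 0.05) fell less, and the list median was -0.32. LSI2 (Os03g0107300) stood at 1433 ± 39.3 CPM in WT root and 1476 ± 9.11 CPM in f3h root. The root cell marker list passed camera (adjusted p = 0.00920), but not with an estimated correlation (adjusted p = 0.216).

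In the photosynthesis list, 18 of 19 tested members rose in f3h root, also when adjusted over the list alone, with a median log2 fold change of 3.60. CAB2R stood at 1.57 ± 0.229 CPM in WT root and 24.3 ± 1.36 CPM in f3h root (log2 3.92 ± 0.17), CAB1R at 0.928 ± 0.296 and 18.1 ± 1.79 CPM (log2 4.24 ± 0.22), and RCA at 2.42 ± 0.689 and 21.3 ± 0.667 CPM (log2 3.11 ± 0.18), against 16679, 9987 and 9870 CPM in WT leaf. This list passed camera also with an estimated correlation (adjusted p = 1.85e-10 and 0.0323). It moved together with other leaf transcripts. Over 69 genes with at least 200 CPM in f3h leaf and a WT root level under 0.05% of it, the median level, relative to leaf of the same genotype, was 0.0135% to 0.0167% in the WT root libraries and 0.210% to 0.227% in the f3h root libraries, and 100% of these genes were higher in f3h root. In chlorophyll synthesis 4 of 5 rose, also when adjusted over the list alone, among them CHLH (Os03g0323200, log2 1.24 ± 0.22) and PORB (log2 2.65 ± 0.62). CHLH stood at 3.15 and 7.59 CPM in WT and f3h root, against 1100 CPM in f3h leaf. PORB stood at 0.258 and 1.70 CPM in WT and f3h root, against 619 CPM in f3h leaf. The list did not pass camera (adjusted p = 0.0723).

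Of the low oxygen genes, 5 of 7 fell in root and 1 rose, also when adjusted over the list alone. ADH2 (Os11g0210500) fell from 3853 ± 105 to 2015 ± 19.5 CPM (log2 -0.96 ± 0.03), ADH1 from 734 ± 18.8 to 353 ± 8.17 CPM (log2 -1.08 ± 0.04) and HB1, at 979 ± 29.7 CPM in WT root, fell too (log2 -0.56 ± 0.04), while SUS1 rose (log2 0.69 ± 0.05). In nitrogen uptake and assimilation, 6 of 10 fell and 1 rose over all genes tested, and 7 fell and 1 rose when adjusted over the list alone. The nitrate transporter NRT2.3 (Os01g0704100, log2 -2.80 ± 0.30), its partner NAR2.1 (Os02g0595900, log2 -2.37 ± 0.35) and glutamine synthetase GS1;2 (Os03g0223400, log2 -1.24 ± 0.05) fell. In jasmonate synthesis and signalling, 8 of 13 fell and 2 rose, also when adjusted over the list alone, with TIFY11A (log2 -2.71 ± 0.16) and TIFY11B (Os03g0181100, log2 -2.57 ± 0.08) falling. Of the antioxidant enzymes 5 of 8 fell and 1 rose over all genes tested, and 5 fell and 2 rose when adjusted over the list alone, with the catalase CATA (Os02g0115700) falling from 307 ± 0.982 to 90.7 ± 3.14 CPM (log2 -1.79 ± 0.05). In phosphate starvation 6 of 10 fell over all genes tested, and 7 fell and 2 rose when adjusted over the list alone. The phosphate exporter PHO1;2 (Os02g0809800) fell from 772 ± 46.6 to 339 ± 4.34 CPM (log2 -1.22 ± 0.04). SPX2 fell too (log2 -3.75 ± 0.70), from 137 to 9 counts over the group. These 5 lists passed camera (adjusted p = 0.000955, 0.00738, 0.0107, 0.0181 and 0.0189, in this order), and none did with an estimated correlation (adjusted p = 0.124, 0.124, 0.193, 0.124 and 0.124). With checked members only, the phosphate list did not pass either (adjusted p = 0.09997 over 7 members).

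Phytoalexin genes gave 2 that rose and 2 that fell of 8 in root (camera adjusted p = 0.634). The diterpene synthase KSL4 (Os04g0179700) rose (log2 1.35 ± 0.38) and lost its call in a fit of all 12 libraries (adjusted p = 0.0836). Pathogenesis related and salicylate genes gave 3 and 3 of 6 (adjusted p = 0.806), with NPR1 rising (log2 0.85 ± 0.07), and their median (-0.01), mean (0.09) and test (down) differed in sign, the median turning positive with upper quartile normalization. Circadian clock genes gave 2 that rose, PRR37 (log2 0.84 ± 0.10) among them, and 5 that fell of 12 (camera adjusted p = 0.211). Of the heat shock genes 1 of 7 fell, HSP82 (Os08g0500700), and the list did not pass camera (adjusted p = 0.369). The counts of these 4 lists were the same when adjusted over the list alone. Over all genes, 6130 rose and 6232 fell in f3h root, 12362 of 24583 tested (50.3%), a background for the list counts in root. With an absolute log2 fold change of at least 1 the counts were 1116 and 2394. The libraries of the genotypes did not overlap for 57.2% of genes, against 10% by chance. Without genes at least 64-fold higher in WT leaf than in WT root, an alternative chosen after the data were seen, 5967 rose and 6215 fell. Of loci without a checked name, Os03g0115800 (377 ± 19.1 CPM) and Os07g0115200 (89.9 ± 2.03 CPM) were read in f3h root and had no count in WT root, at least 10627-fold and 2527-fold higher. Os09g0522100 (41.9 ± 4.11 CPM in WT root) and Os12g0630200 (31.4 ± 2.60 CPM) had no count in f3h root, at least 1082-fold and 808-fold lower.

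**Figure D2:**
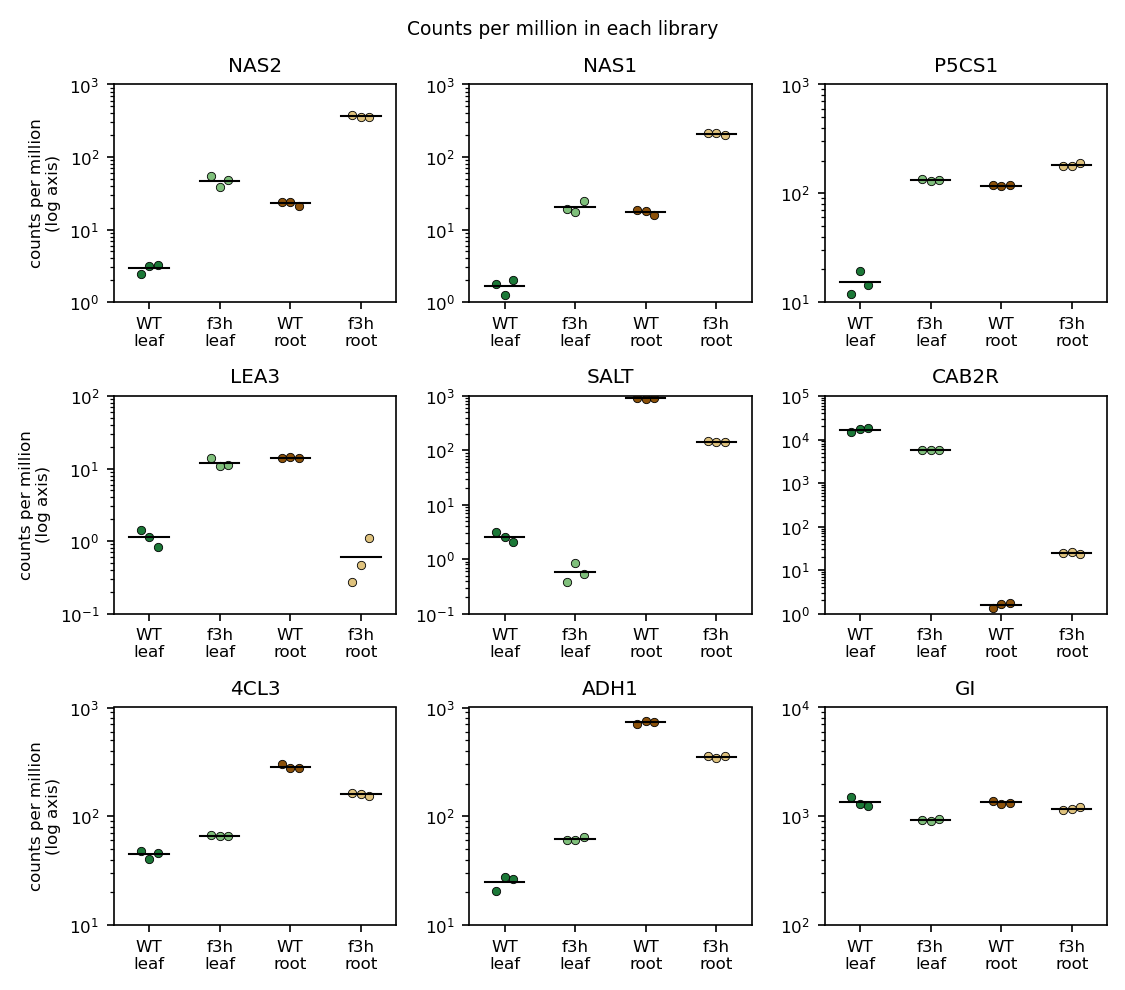
CPM (log axis) of 9 genes in each of the 12 libraries, as points, with the group mean as a bar. NAS2 was higher in f3h in both organs (47.2 against 2.96 CPM in leaf, 364 against 23.1 in root), whereas LEA3 was higher in f3h leaf (11.9 against 1.13) and lower in f3h root (0.611 CPM, log2 -4.57).

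The effects in the organs were then compared by testing the difference itself. LEA3 rose in f3h leaf and fell in f3h root, a difference of -8.01 ± 0.44 on the log2 scale (root effect minus leaf effect, adjusted p = 4.11e-09). TIFY11A (difference -4.58 ± 0.31), ADH1 (-2.43 ± 0.13) and 4CL3 (-1.47 ± 0.11) also rose in leaf and fell in root. CAB2R went the other way (5.42 ± 0.16). Its root levels (1.57 and 24.3 CPM in WT and f3h) were far under those in leaf, and it moved there with other leaf transcripts. The copalyl diphosphate synthase CPS4 fell in leaf and stood at 8.53 ± 0.575 and 9.01 ± 0.872 CPM in WT and f3h root (difference 4.83 ± 0.37). NAS2 and NAS1 rose in both organs (differences -0.07 and -0.10, neither past the threshold), and CSLD1, SALT and SPX2 fell in both. SPX2 fell further in root (difference -1.99 ± 0.67, adjusted p = 0.0333), but had only 9 counts over f3h root.

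By list, the f3h effect was lower in root than in leaf for phenylpropanoid and lignin synthesis (13 of 20 genes lower and 1 higher, adjusted p = 4.54e-07, and 0.0237 with an estimated correlation), phosphate starvation (6 of 10 lower, 8 when adjusted over the list alone, adjusted p = 0.00109 and 0.0237), antioxidant enzymes (5 of 8 lower and 1 higher, adjusted p = 0.00109 and 0.0296), low oxygen (5 of 7 lower, adjusted p = 0.00195 and 0.0296) and water deficit (10 of 13 lower, adjusted p = 2.48e-07 and 0.0180). It was higher in root for photosynthesis (21 of 22, adjusted p = 1.18e-08 and 0.0237), the list that moved with other leaf transcripts in root. Flavonoid synthesis (6 of 12 lower and 1 higher, adjusted p = 0.00837), the circadian clock (7 of 12 higher, adjusted p = 0.00787) and phytoalexin synthesis (7 of 11 higher and 1 lower, 8 and 1 when adjusted over the list alone, adjusted p = 0.0167) lost their calls with an estimated correlation (adjusted p = 0.0896, 0.143 and 0.173). Where not stated, the counts were the same when adjusted over the list alone. In the iron uptake list 2 of 12 genes were higher, NAAT1 (2.59 ± 0.16) among them, and 4 lower, and the list did not pass camera in either direction (adjusted p = 0.705). The other 7 lists did not pass.

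Over all genes, the effect differed between organs for 8806 of 26328 tested (33.4%), 4214 with a higher and 4592 with a lower effect in root. Of 20896 genes tested in both organs, 1257 rose in both and 1166 fell in both, where independent lists would share 992 and 925. A further 1049 rose in leaf and fell in root (934 for independent lists), and 959 fell in leaf and rose in root (983). Across these genes, which are not independent replicates, the log2 fold changes in leaf and root had a Pearson r of 0.137 and a Spearman rho of 0.0629, and 52.9% had the same sign. The organs share no control libraries.

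**Figure D3:**
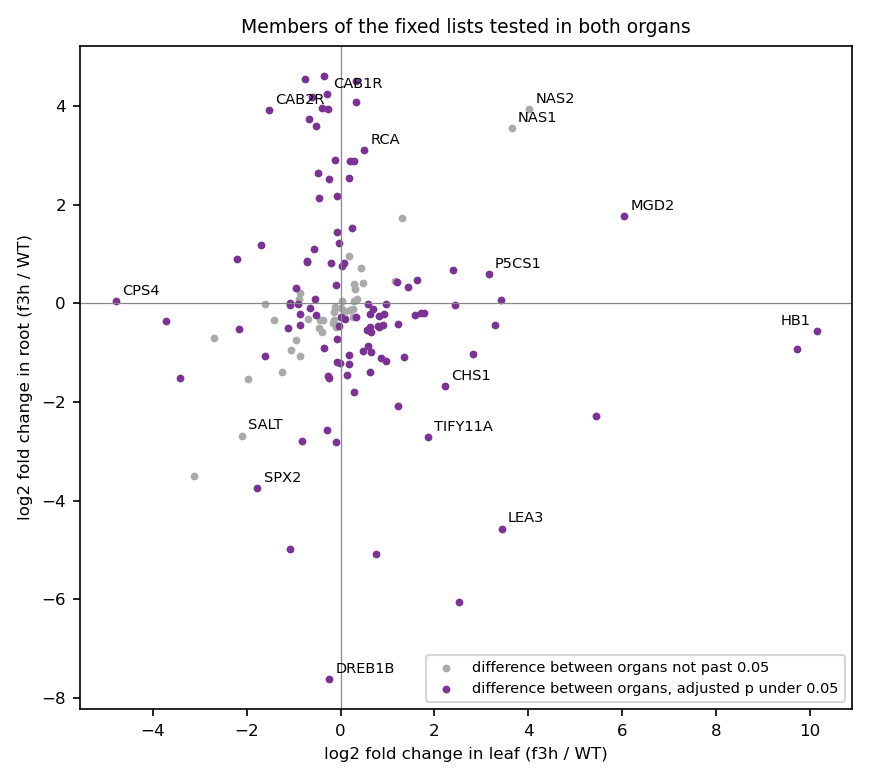
Log2 fold change (f3h over WT) in root against leaf for 149 members of the fixed lists tested in both organs, 109 of them with a difference between organs at an adjusted p under 0.05 (purple). NAS2 (4.02 and 3.95) and NAS1 lie in the upper right, LEA3 (3.43 and -4.57) in the lower right and CAB2R (-1.52 and 3.92) in the upper left. CAB2R stood at 1.57 and 24.3 CPM in WT and f3h root, far under its leaf levels.

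The comparison of WT root with WT leaf gave the background organ difference against which the genotype effects can be set. Photosynthesis genes were higher in leaf and root cell markers in root. CAB2R was at 16679 ± 1875 CPM in leaf and 1.57 ± 0.229 CPM in root (log2 -13.93 ± 0.23), and RCA at 9870 ± 1210 and 2.42 ± 0.689 CPM (log2 -12.56 ± 0.26). The silicon transporter LSI2 (Os03g0107300, 1433 ± 39.3 CPM), HB1 and CASP1 were read in WT root with no count in WT leaf, at least 47739-fold, 32604-fold and 2868-fold higher, and LSI1 (Os02g0745100) was higher by 7.11 ± 0.25 on the log2 scale. ADH2 (log2 12.89 ± 0.22) and, in leaf, PORB (log2 -12.27 ± 0.19) were among the largest named differences.

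All 22 tested photosynthesis genes and 6 of 6 chlorophyll synthesis genes were called higher in WT leaf, and 11 of 12 root cell markers and 7 of 7 low oxygen genes were called higher in WT root with the fold limit, also when adjusted over the list alone. Medians were -13.21, -8.18, 7.24 and 6.72, and with members at a count of 0 set to their bound the last 2 became 6.95 and 5.53. Of the iron uptake genes 6 of 11 were higher in root, YSL15 (Os02g0650300, log2 8.62 ± 0.39), NAS1 and NAS2 among them, and 4 in leaf, such as NAAT1 (log2 -2.26 ± 0.15). In flavonoid synthesis 5 of 12 were higher in root and 3 in leaf, CHS1 (log2 -3.36 ± 0.37) among the latter, while CHI (log2 -0.94 ± 0.22) stayed under the fold limit. The counts of both lists were the same when adjusted over the list alone. Camera called 8 lists, the others being phenylpropanoid synthesis, cell cycle and water deficit (higher in root) and jasmonate (higher in leaf), and photosynthesis had the lowest adjusted p (3.73e-11), which was 0.119 with an estimated correlation, under which no list passed. Over all genes, 7548 were called at least 2-fold higher in root and 5777 in leaf, together 52.8% of 25229 tested. For 77.7% of genes the organs' libraries had no overlap, against 10% by chance. The median log2 difference of all genes was 0.11, and 0.32 with upper quartile normalization, a shift of 0.22.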

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

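The share of leaf genes near the median share and the comparison of the photosynthesis list with all genes in root were tests chosen only after the result was seen. Every value of the next 3 paragraphs stands here because the f3h effect differed between organs by the interaction test (root effect minus leaf effect, log2), and each is given as that difference.

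For all genes tested, the effect differed for 8806. The medians of the lists that differed were -1.79 for flavonoid synthesis, -1.38 for phenylpropanoid and lignin synthesis, 2.79 for phytoalexin synthesis, -1.37 for phosphate starvation, 3.38 for photosynthesis, 0.63 for the circadian clock, -0.75 for antioxidant enzymes, -1.46 for low oxygen and -2.72 for water deficit. The calls of flavonoid synthesis, phytoalexin synthesis and the circadian clock were lost (adjusted p = 0.0896, 0.173 and 0.143 with an estimated correlation). Of 40 assignments of genotype within each organ, 1, the real one, gave as many genes as 8806. The highest of the others gave 2792. Each of the others mixed WT and f3h libraries in at least 1 organ. The genotype difference then widens the spread within groups and lowers the calls, so this comparison cannot tell whether chance gives as many.

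Genes with a lower effect in root were LEA3 (-8.01), DREB1B (-7.38), TIFY11A (-4.58), CHS1 (-3.90), ADH1 (-2.43), SPX2 (-1.99), the nitrate transporter NRT2.3 (-1.98), SUS1 (-1.70), 4CL3 (-1.47), ADH2 (-1.46), SPX1 (-1.35), CAD2 (-1.30), CHI (-1.24), PHO1;2 (-1.21), CATB (-1.16), SODA (-1.10), the flavanone 3-hydroxylase locus Os10g0536400 (-0.81) and CHLD (-0.62). HB1 (-10.83) and RAB16D (-9.03) belong here too, but each had a group at or near a count of 0, so these fitted values depend on the prior count. Without f3h leaf replicate 1 the RAB16D difference did not pass (-6.27, adjusted p = 0.9999). The SPX2 difference passed close to the threshold (adjusted p = 0.0333), with 9 counts over f3h root, and was not re-run under the alternatives.

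Genes with a higher effect in root were CAB2R (5.42), CPS4 (4.83), CAB1R (4.51), PORB (3.10), RCA (2.60), CYP99A3 (1.63), NPR1 (1.56), PRR37 (1.55), CDKB1;1 (1.03), the F3H-like locus Os03g0122300 (0.63), TIFY10B (0.42) and GI (0.29). GI (adjusted p = 0.0482), CYP99A3 (0.0434) and Os03g0122300 (0.0235) passed close to the threshold. Their differences were not re-run under the alternatives. The leaf call of Os03g0122300 was lost when any f3h leaf library was left out. Without f3h root replicate 1, CYP99A3 passed as a fall in root (log2 -1.19, adjusted p = 0.00339). CPS2 (6.15) had 6 counts over WT root and 30 over f3h root, too few for a separate test in root, so its value depends on the prior count as well. The crown root gene WOX11 (5.40) was too low in leaf for a separate test, and its value depends on the prior count. The WOX11 difference was lost under limma voom (adjusted p = 0.103) and without WT leaf replicate 3 (adjusted p = 0.0513), and that of CAB1R under limma voom (adjusted p = 0.0655).

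Photosynthesis genes, and the chlorophyll synthesis gene PORB, were higher in f3h root at levels far under those in leaf. A scaling factor moves all genes of a library alike, so it does not account for a list whose median lay 3.59 above that of all genes in root (lower quartile of its members 2.70). A small share of leaf RNA in the f3h root libraries, or of reads assigned to them from leaf libraries, is a candidate explanation. The 69 leaf genes had been chosen by a low WT root level, which favours a rise. Of them, 95.65% lay within 4-fold of a median implied share of 0.207% of the f3h leaf level. Photosynthesis genes had 1.06 times the share of other leaf genes (interval 0.717 to 1.26). The spread of shares on the log2 scale was 0.819 against the f3h leaf profile and 0.618 against that of WT leaf, and Os09g0537700, at 14247 CPM in f3h leaf, gave a share of only 0.0218%, so the profile of f3h leaf was not the closer one. A genotype effect on these genes in root was not tested apart from this and stays open.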

How the results depend on the processing

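The alternatives without genes read in one genotype only, without genes at least 64-fold higher in WT leaf than in WT root, and with only list members whose names were checked were chosen after seeing the data. With an absolute log2 fold change of at least 1, counts fell to 3440 in leaf, 3510 in root and 5273 for the difference between organs, since a fold limit removes smaller changes. With an estimated correlation per list, camera called 0 lists in leaf (2 at an unadjusted p under 0.05, and 12 with fry) and 1 in root, photosynthesis (4 unadjusted). The correlation between organs was 0.213 over genes with an average log2 CPM of at least 3, and 0.113 to 0.139 with 1 library left out. The cause was not tested for the lists or the correlation.

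Under the other alternatives, counts stayed within 1.5 times those reported. They ranged with 1 library left out from 5790 (without f3h leaf replicate 2) to 11144 (without WT leaf replicate 1) in leaf, from 10937 to 11846 in root, from 7709 to 10584 for the difference between organs and from 13221 to 13679 between organs in WT. With the replicate number as a block, 7449 genes were called in leaf, 12225 in root and 8291 for the difference between organs. Fitting all 12 libraries gave 9964 in leaf and 9108 in root. Without genes read in one genotype only, leaf gave 8075 and root 12247. Without the 64-fold leaf genes root gave 12182 genes and 11 lists, the photosynthesis list then having fewer than 3 members. With checked members only, camera called 5 lists in leaf, photosynthesis losing its call (adjusted p = 0.791), and 10 in root, phosphate starvation losing its call (adjusted p = 0.09997). Flavonoid synthesis had fewer than 3 checked members tested and could not be run so.

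Named genes called were followed through refits that tested them (other normalizations, filters and tools, the block, all 12 libraries, and each library left out). Of these, 51 of 52 in leaf, 55 of 64 in root and 20 of 20 between organs in WT stayed past the threshold. For the difference between organs 7 of 10 did. The 10 had the largest terms, and the other genes named as differing were not re-run. In these refits 0 changed direction. The fold limit was not applied to named genes. GI in leaf (log2 -0.52), for example, lies under it. In root, the phosphate transporter PT6 (adjusted p = 0.0504), NRAMP5 (0.0523), SHR1 (0.0856), CATB (0.144), CYP76M8 (0.116) and KSL4 lost their calls in the fit of all 12 libraries, SPX1 without WT root replicate 1 (0.0598) or f3h root replicate 2 (0.0569), and CHLI without f3h root replicate 1 (0.221). The lists built from gene descriptions and the correction for gene length or GC content were not run, as the reference pairs neither with these loci. Depth limits the reading of genes under 3 counts over a group.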

Other observations

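The sharing of genes read in one genotype only between organs was a test chosen only after the result was seen. Genes with at most 3 counts over one genotype and at least 1 CPM in the other numbered 63 read in f3h only and 19 read in WT only in leaf, and 42 and 35 in root. In both organs 9 were read in f3h only, Os03g0115800 (105 CPM in leaf, 377 CPM in root) and Os03g0629800 (29.8 CPM in root) among them, and 0 in WT only. A stable difference in genome sequence between the lines is a candidate explanation that these data do not decide. Of 47 leaf genes of this kind that were present in root, 19.15% were read in the same genotype only there (95% interval 9.15% to 33.3%). Taken from root, the share was 36% of 25 genes present in leaf. Both shares depend on the limit of 3 counts. Os08g0410900, with 0 counts in WT leaf, had 6 counts over WT root and 1189 over f3h root. It was therefore not counted as shared, although its root levels differed in the same direction. Of 562 other genes changed at least 8-fold in leaf, 7.83% also changed at least 8-fold the same way in root. These 562 were not limited to genes present in root and were judged by fold change, so their share is not a like baseline. The 9 genes lay on 7 chromosomes with 0 neighbouring pairs, and all of 10000 random draws had at least 0 pairs (a share of 1). A share of 0.05 or more had been set beforehand as counting against clustering, but random draws gave a mean of 0.0322 pairs, so 0 pairs among 9 genes decides nothing.

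Of 46 mitochondrial genes, 9 were high enough to be tested in root, and these 9 rose in f3h root. All 46 together made up 0.000115% of counts in WT root and 0.00171% in f3h root. Levels in WT root were thus near 0, and the fitted median log2 fold change of 5.30 depends on the prior count. With WT root so low, a gene could pass the count filter mainly by being high in f3h root. That all 9 rose was therefore largely set by the filter. Of these 9, cob, a cytochrome b gene, had 24 counts over WT root and 304 over f3h root (log2 3.72 ± 0.54, adjusted p = 1.24e-06). Of 6 plastid genes tested in leaf, psaC fell (log2 -1.07 ± 0.24). Such transcripts are read poorly from libraries made for polyadenylated RNA.

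WT leaf replicate 1 differed from replicates 2 and 3. CAB1R stood at 5924 CPM in it and at 11657 and 12380 CPM in the others, the clock gene ELF3-1 at 110, 65.8 and 58.2 CPM, and the catalase CATA at 981, 557 and 586 CPM. Without it NRT2.3 (log2 -1.12, adjusted p = 0.00936) passed in leaf.

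For the leaf, root and WT organ comparisons, 10 splits of the 6 libraries are too few for a share under 0.05. The real splits gave 8188, 12362 and 13325 genes, 1 of 10 splits each, and the highest other gave 0 with edgeR in each (454, 278 and 52 at an unadjusted p under 0.05). Other tools were not run on these splits. The other splits mix the groups compared, so the difference between them widens the spread within each side. Their 0 calls therefore do not decide about chance.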
